A study of Caenorhabditis elegans with 2 samples.

How the data were processed

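Chromatin immunoprecipitation followed by sequencing (ChIP-seq) of a GFP-tagged transcription factor was carried out on whole Caenorhabditis elegans larvae of the first stage, L1, of mixed sex. The strain, OP355, carries an integrated transgene, wgIs355, in an unc-119 mutant background. Per the labels there were 2 libraries, biological replicates 1 and 2, each with 1 technical replicate, and a size range of 150 to 350 bp. The labels disagree on the tagged gene. The antibody and source fields name mdl-1, while the description names ZK337.2, which the annotation calls klu-1. Neither name was used to choose or group the libraries.

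The authors' files are lists of regions, for genome builds ce11 and ce10. Per the readme texts deposited with the lists, regions were derived from alignments together with a control, and the thresholded list was made from the pooled list and both replicate lists. For each build there was a relaxed list for each replicate and for the pooled data, of 30000 regions each, meant as input to an irreproducible discovery rate comparison, and a thresholded list. The region's signal is a deposited value that is never negative, and its scaling is not given in the sources used here. A second deposited column, the score in the place of a q value, went below 0 in the relaxed ce11 pooled list (-0.114 to 2.05), so it was not read as a q value and entered no test. The deposited p column held no values. The aligner, the peak caller, their versions and the threshold are not given in the sources used here. The control data were not analysed here. The files give no read counts, so the depth of the libraries is unknown, and a difference in depth between them could change their signal and the ranks of weak regions.

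Regions were taken in ce11, whose coordinates fit the reference assembly used, WBcel235. The last region on each of the 6 chromosomes ended inside the reference chromosome. Gene positions came from Ensembl release 115, with 19973 protein-coding genes on those chromosomes. Of the genes matched by symbol to the RefSeq table of the same assembly, 96.4% started at the same base. Coordinates are 1-based, and no coordinate was converted between builds. The summit is the point that the authors' list marks within each region. Regions of both replicates were matched when their summit windows of 100 bp either side overlapped, that is, when summits lay at most 200 bp apart.

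The background for tests of thresholded regions was the 29741 relaxed pooled regions that did not pass. A promoter window ran from 1000 bp upstream to 500 bp downstream of the 5' end of a protein-coding gene. Sequences were searched on both strands within 50 bp of the summit. Tests of shares were Fisher's exact tests, two-sided. Benjamini-Hochberg adjustment was over 6 chromosomes, 7 sequences, 25 gene lists, 6 classes of annotated feature, 7 classes of small RNA and other non-coding gene, or 2080 sequences of 6 bases. Replicate agreement and promoter location were single tests with no adjustment. A gene list was tested when 5 or more of its genes were in the background. Annotated features were compared with a random draw of 3000 background regions. The neighbourhood of a gene, 20 kb either side, was compared with 10000 random windows of the same width on its chromosome in a one-sided permutation test. Intervals are 95% intervals, exact Clopper-Pearson for shares and exact conditional for odds ratios, and cover counting error only. Odds ratios over GC content used the Mantel-Haenszel estimate over bins of 2 percentage points, and their 95% intervals are large-sample ones on the log scale, not exact. Regions are not independent replicates, so these p-values describe the lists of these 2 libraries, not variation between cultures.

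Genes were named by a rule fixed before the data were examined. It took the genes of the 25 thresholded regions with the highest signal, assigned by promoter window or otherwise by the nearest 5' end, and up to 4 bound members of each gene list by signal. The rule also always took mdl-1, ZK337.2, unc-119, mxl-1, mxl-2, mxl-3, mml-1 and hlh-30. The gene lists, the 7 sequences and the alternatives were fixed at the same time, except for the odds ratios over GC content and the merging of summits within 1000 bp at small RNA genes, which were added after seeing the data. Alternatives changed the build, the overlap rule, the number of strongest regions, the promoter and sequence windows, the background, the threshold and the replicates included.

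The tests were run on simulated data before use. With random sets of 259 regions, 6 of 100 simulations passed 0.05 for promoter location, 6 for chromosome X and 2 for CACGTG. With regions carrying the feature given 4 times the weight, 100 of 100 simulations were called in each of these tests, with median odds ratios of 4.04, 4.06 and 4.05. These exceed the odds ratios of the real data for promoter location (2.06) and chromosome X (1.63), so power at those sizes was not measured. Chromosome X and CACGTG were called here on the p before adjustment. The neighbourhood test, run on replicate 1 with 1000 random windows, passed at 7 of 100 random places and at 98 of 100 after 20 regions were added there. For gene lists, 1 of 100 simulations had any list past the adjusted threshold, and 7 planted ribosomal protein genes were called in 100 of 100. The real data also had 7 such genes, so the planted outcome was fixed in advance and says nothing about smaller effects. Replicate agreement passed in 2 of 100 simulations with shuffled ranks and in 100 of 100 with 100 shared regions planted. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.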

Results

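Binding of a GFP-tagged transcription factor was mapped in L1 larvae of strain OP355 in 2 biological replicates, with no other condition to compare. The comparisons that this design allows are between the replicates, and between regions that passed the authors' threshold and those that did not. Depth was unknown, since the files give no read counts. The labels name 2 different tagged genes, mdl-1 and ZK337.2 (klu-1), so the neighbourhoods of both genes were examined first. MDL-1 is a basic helix-loop-helix leucine zipper protein related to mammalian MAD proteins, which pair with MAX-like partners and bind E-box sequences.

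The region with the highest signal in the whole data set lay at the 5' end of mdl-1 (WBGene00003163, chromosome X, 6742351 to 6743899, plus strand). It spanned 6742131 to 6742365 on ce11, in intergenic sequence, with its summit 97 bp upstream of the 5' end. Its signal was 503.3 in the pooled list, 190.5 in replicate 1 and 294.5 in replicate 2, and it ranked 1 in each list. Within 20 kb of mdl-1 the pooled relaxed list held 36 regions, against a median of 14 in random windows of chromosome X (permutation p = 0.0001, the smallest that 10000 windows can give). Their mean signal was 76.7, against a median of 21.95 (permutation p = 0.0012). Replicate 1 had 37 regions there with a mean signal of 37.7, and replicate 2 had 36 with a mean of 40.3. Of the thresholded regions, 13 lay in this window, spread over 25.3 kb from 6725146 to 6750461, and 5 of them were among the 25 with the highest signal. One, ranked 4, lay in an intron of abts-4, and another, ranked 8, in an intron of mdl-1 itself.

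The other gene named in the labels, klu-1 (WBGene00013970, chromosome I, 14975419 to 14980596), had no thresholded region within 50 kb. The pooled list held 15 regions within 20 kb, against a median of 13 (permutation p = 0.363), with a mean signal of 22.03 against 21.63 (permutation p = 0.4004). At unc-119 (WBGene00006843, chromosome III, 10902641 to 10908935), the gene mutated in this strain, there were 18 regions against a median of 14 (permutation p = 0.212), with a mean signal of 19.96 against 21.76. No thresholded region lay within 50 kb of unc-119.

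**Figure D1:**
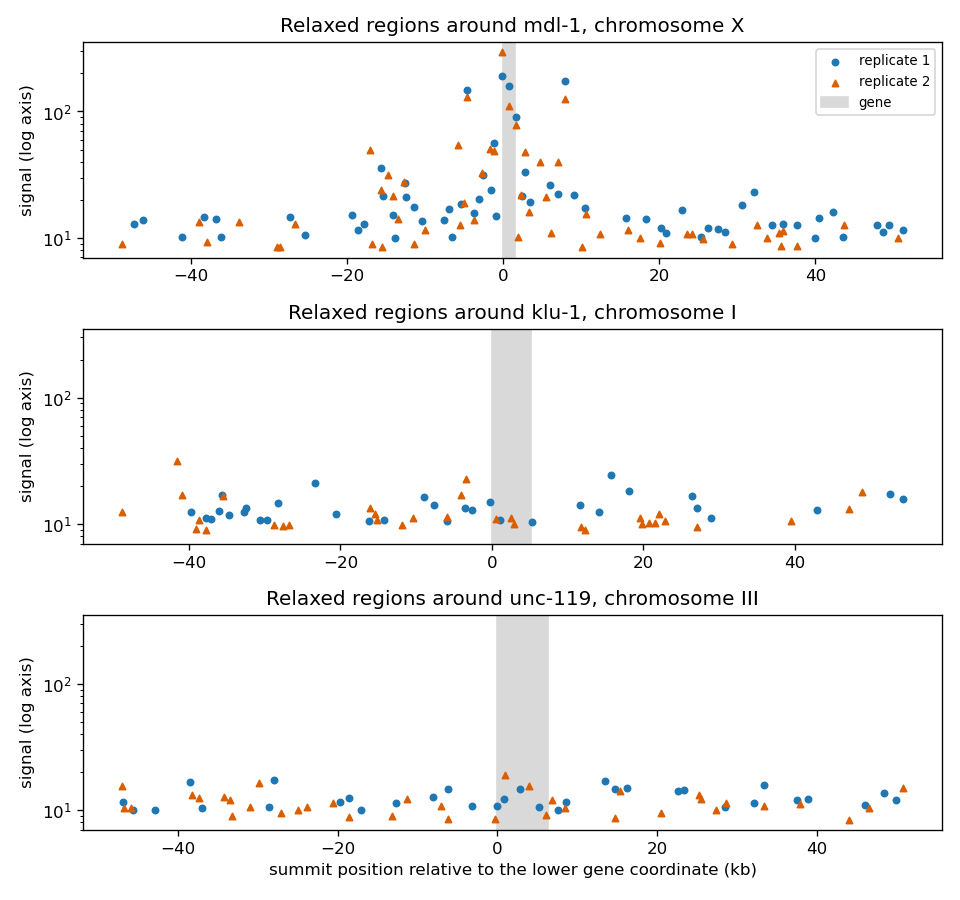
Signal of relaxed regions (log axis) against summit position in kb for 50 kb either side of mdl-1, klu-1 and unc-119, with replicate 1 as circles, replicate 2 as triangles and the gene shaded. Signal at mdl-1 reached 190.5 in replicate 1 and 294.5 in replicate 2, while within 20 kb of klu-1 it reached 24.6 and 22.7.

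The authors' thresholded list held 259 regions, which were exactly the 259 regions of highest signal in the pooled list, from 503.3 down to 49.8. The median signal was 68.3, against 20.3 among the regions that did not pass. After mdl-1, the next strongest was at 12583608 to 12583760 on chromosome III, with a signal of 340.2. It was intergenic, and its nearest protein-coding 5' end, 8284 bp away, was that of aakg-1, a gamma subunit of AMP-activated protein kinase. Another, ranked 5 (signal 280.3) and also near mdl-1, was at 6737692 to 6737847 on chromosome X, with R03E9.2 as the nearest protein-coding gene. The third, at 20778337 to 20778445 on chromosome V with a signal of 299.5, lay 1999 bp upstream of hif-1, the hypoxia-inducible factor. A region 1765 bp upstream of egl-9, the prolyl hydroxylase that acts on HIF-1, ranked 24 with a signal of 159.8.

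Several of the other strong regions also lay outside promoter windows. They included regions nearest to gdh-1, a glutamate dehydrogenase (signal 278.4), T04C4.3 (274.3), mtm-3, a myotubularin-related phosphatase (257.6), ppm-2 (211.6), nhr-34 (205.5) and ogt-1, the O-GlcNAc transferase (182.2). Regions in introns lay in Y43F8B.2 (220.9), nhr-19 (217.0), Y111B2A.12 (188.0) and F09A5.3 (166.7). In promoter windows, the strong regions were those of tasp-1 and K01G5.10 (221.9), epn-1, an epsin (216.3), C36E6.2 (194.5), epg-7 (189.6), tos-1 (173.0), iff-2 and F54C9.14 (165.0) and C09E9.1 (158.6).

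Both replicates were compared on their own strongest regions. Of the 259 strongest of replicate 2, 124 (47.9%, 95% interval 41.7% to 54.1%) matched one of the 259 strongest of replicate 1. Among its other 29741 regions 0.316% did (Fisher's exact test, odds ratio 290, p = 9.2e-209). Of the thresholded regions, 256 had a matching region in the relaxed list of replicate 1 and 258 in that of replicate 2. However, 167 of them (64.5%) were among the 259 strongest of replicate 1, 189 (73.0%) among those of replicate 2, and 121 (46.7%) among both. Over the 7179 regions matched between the relaxed lists, signal correlated weakly across regions (Spearman rho 0.186), and 3627 regions matched after one list was moved by 10 kb. Over the 254 matched regions at thresholded sites rho was 0.438. The thresholded list was made using both replicate lists, so its matches and this rho are not independent measures of agreement. Regions are not independent replicates, so no p is given for these correlations.

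**Figure D2:**
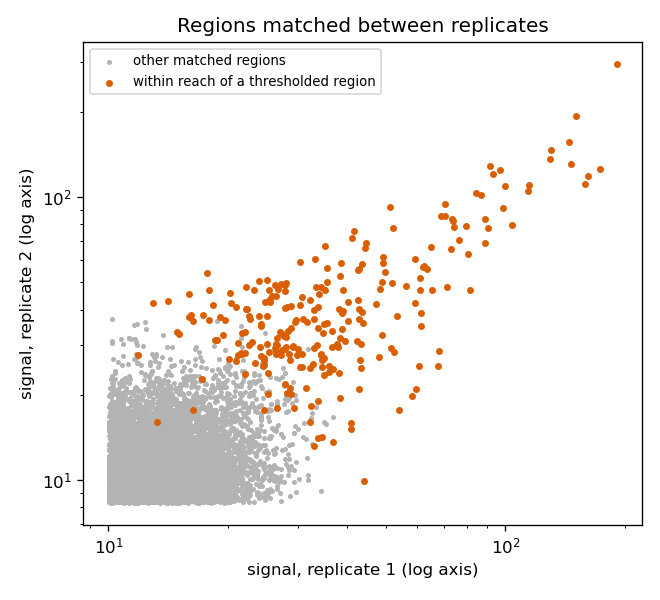
Signal in replicate 2 against signal in replicate 1 (both log axes) for the 7179 matched regions, with those at thresholded sites in orange. The 254 orange points follow a rank correlation of 0.438, and all matched regions together one of 0.186. The thresholded sites were chosen using both replicates.

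Thresholded summits lay in promoter windows more often than the others did. The share was 118 of 259 (45.6%) against 28.8% (Fisher's exact test, odds ratio 2.06, 95% interval 1.60 to 2.66, p = 1.7e-08). By annotation, 57.9% of thresholded summits were intergenic, against 33.5% of the regions drawn from the background. Coding exons held 1.93% against 23.7% (Fisher's exact test, odds ratio 0.0635, adjusted p = 1.7e-21). Introns held 27.03% against 34.4%, and 5' UTRs 3.86% against 1.53%. Non-coding genes held 8.49% against 3.93%, and 3' UTRs 0.772% against 3%.

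Chromosome X held 75 thresholded regions (28.96%), against 20.04% of the background (Fisher's exact test, odds ratio 1.63, 95% interval 1.22 to 2.14, adjusted p = 0.00356). Chromosomes IV and V held fewer than the background share, with odds ratios of 0.630 and 0.650 (Fisher's exact test, adjusted p = 0.0372 for each). The 13 regions near mdl-1 are all on chromosome X. Without regions within 50 kb of mdl-1 and klu-1, the share on X was 25.203% against 19.96%, with an odds ratio of 1.35 that did not pass the adjusted threshold (Fisher's exact test, adjusted p = 0.0678). Chromosome III, with an odds ratio of 1.45, and chromosomes IV and V did not pass either, at the same adjusted p.

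**Figure D3:**
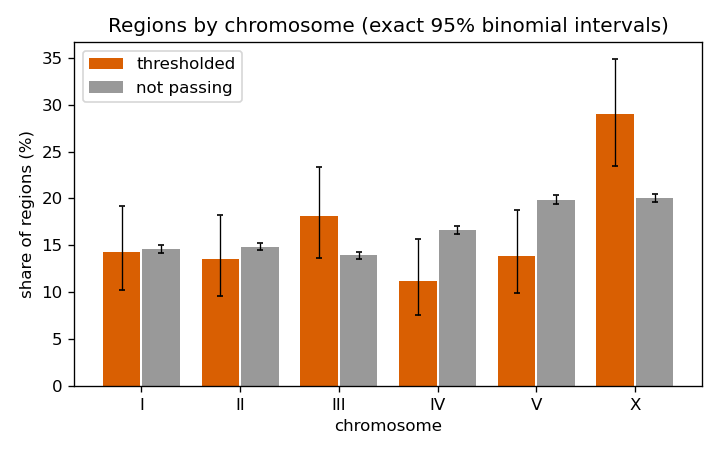
Share of regions (%) on each chromosome for the 259 thresholded regions (orange) and the 29741 regions that did not pass (grey), with exact 95% binomial intervals. Chromosome X stands at 28.96% against 20.04%, and this includes 13 thresholded regions near mdl-1.

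The E-box CACGTG, fixed in advance for the mdl-1 label, was found within 50 bp of 65 of 259 thresholded summits (25.097%) and of 2.296% of the other summits (Fisher's exact test, odds ratio 14.3, 95% interval 10.5 to 19.2, adjusted p = 4.3e-45). The related E-box CATGTG stood at 9.65% against 3.45% (Fisher's exact test, odds ratio 2.99, adjusted p = 1.2e-05). The repeat GAGAGAG stood at 17.4% against 1.88% (Fisher's exact test, odds ratio 10.98, adjusted p = 3.5e-28). Over strata of GC content, the odds ratios were lower, at 6.34 (95% interval 4.64 to 8.67) for CACGTG, 2.08 (1.35 to 3.20) for CATGTG and 4.14 (2.92 to 5.86) for GAGAGAG. CAGCTG was more frequent (odds ratio 2.00) and the GATA-type sequence TGATAA less frequent (odds ratio 0.521), with adjusted p = 0.0435 and 0.0298 by Fisher's exact test. Over the same strata neither of these last odds ratios was distinguishable from 1, with values of 0.948 (95% interval 0.507 to 1.77) and 1.18 (0.668 to 2.098). GTAAACA and TGACTCA did not pass, the latter with 0 of 259 summits.

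CACGTG was found at 24 of the 50 strongest regions (48.0%, 95% interval 33.7% to 62.6%), 9 of the next 50 (18%) and 32 of the remaining 159 thresholded regions (20.1%). Among regions ranked 260 to 500, just under the authors' threshold, 15.4% had it (95% interval 11.05% to 20.54%), and among those ranked 5001 to 30000, 2.06%. Of the 120 thresholded regions with a CACGTG within 500 bp, the median distance to the summit was 43 bp. The E-box was at the summits of mdl-1, epg-7, tos-1 and C36E6.2, and at the region ranked 2.

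**Figure D4:**
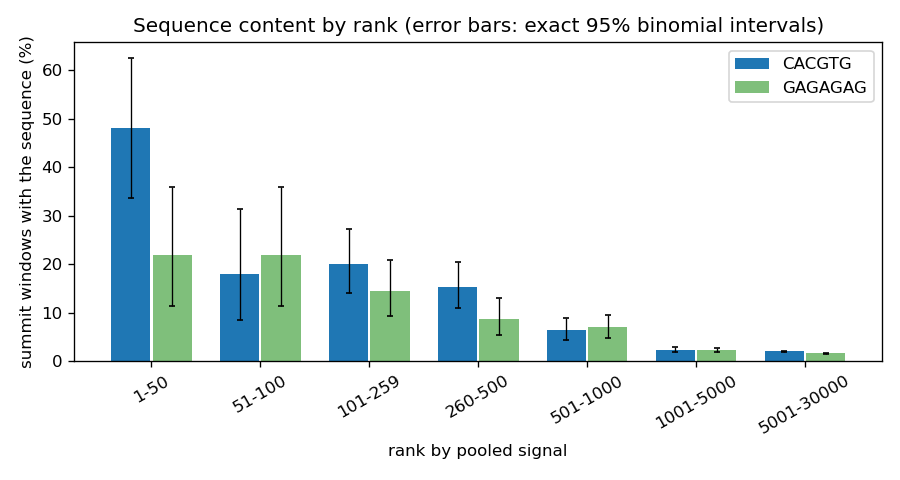
Share of summit windows (%) holding CACGTG (blue) and GAGAGAG (green) by rank of pooled signal, with exact 95% binomial intervals. The CACGTG share falls from 48.0% in the 50 strongest regions to 2.06% in ranks 5001 to 30000.

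The thresholded regions fell in promoter windows of 144 protein-coding genes, which were compared with 8389 genes that had only a non-passing region there. The other 141 thresholded summits lay outside such windows, and a gene is called bound here only by its promoter window. Each gene had a single window, at its outermost annotated 5' end, so transcript starts further inside a gene were not covered. A summit in a 5' UTR of gap-2, 18238 bp from that end, therefore counted as outside. Ribosomal protein genes had the smallest adjusted p, with 7 bound out of 50 in the background (Fisher's exact test, odds ratio 9.92, 95% interval 3.69 to 22.7, adjusted p = 0.000458). The strongest were rpl-15 (signal 118.3), rpl-3 (88.7), rps-1 (71.5) and rps-12 (71.2), and the others were rpl-14, rpl-35 and rpl-12. Translation factors had 3 bound of 19, namely iff-2, which encodes the factor eIF5A (165.0), eef-1A.2, a translation elongation factor (91.2), and eif-2Bgamma (71.1). The summit assigned to eif-2Bgamma lay 965 bp upstream of it and 55 bp from the small nuclear RNA gene sup-39. Autophagy and lysosome genes also had 3 of 19, the autophagy scaffold gene epg-7 (189.6) and the Atg8 homologues lgg-2 (79.3) and lgg-1 (55.7). Both lists had an odds ratio of 11.1 (Fisher's exact test, adjusted p = 0.0312). Each rests on 3 genes and was lost in 4 of 9 alternatives, with odds ratios of 7.23 to 9.18 and 7.46 to 15.4 there. Another of the 9, merging summits within 100 bp, changed no value. Among the bound genes of both lists, only epg-7 had CACGTG within 50 bp of the summit. Of the 7 ribosomal protein genes, only rpl-14 had it. The regions of rpl-15, rpl-3 and rps-1 were among the 259 strongest of both replicates. That of rps-12 was so in replicate 2 only, and that of rpl-14 in replicate 1 only. In replicates 1 and 2 the rpl-35 region ranked 1171 and 272, and that of rpl-12 548 and 377.

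Other lists did not pass. Histones had his-72 (64.3) and his-37 (59.5), with adjusted p = 0.104 by Fisher's exact test. Histones passed, with 2 genes, without replicate 2 and with the nearest gene only (Fisher's exact test, adjusted p = 0.0446 and 0.0462). Proteasome and ubiquitin genes passed, with 3 of 26, without replicate 2 (Fisher's exact test, adjusted p = 0.0446). Chaperones had cct-7 (58.05) and hsp-1 (50.5), with adjusted p = 0.241 by Fisher's exact test. In replicates 1 and 2 the cct-7 region ranked 70 and 19984, that of his-37 87 and 3536, and that of his-72 1834 and 86. Oxidative phosphorylation had cox-5A (80.9) and nduf-2.2 (55.5), and nuclear hormone receptors had nhr-32 (122.2), nhr-1 (63.0) and nhr-49 (52.2). Single bound members were ain-1 (120.4) of the heterochronic genes, ceh-38 (101.7) of the homeobox genes, rpn-11 (69.9) of the proteasome and unc-108 (53.3) of the housekeeping genes. No member had a thresholded summit in its promoter window in 13 lists, namely collagens, insulin signalling and longevity, vacuolar ATPase, ribosome biogenesis, cilia, neurons, pharynx, body wall muscle, hypodermis, intestine, germline and early embryo, cell cycle and DNA replication, and the core of RNA polymerase II and splicing. These lists had between 9 and 58 genes in the background, and for each the interval of the odds ratio included 1. Thresholded summits did lie in introns of members of 2 of these lists, outside their promoter windows. Of the insulin signalling and longevity genes these were aak-2 (signal 71.8), pdk-1 (60.3) and daf-2, the insulin receptor gene (50.1, with CACGTG). Of the cell cycle genes it was cye-1 (49.99), whose region ranked 14944 in replicate 1 and 105 in replicate 2. Among lists with a bound member, further introns with thresholded summits were those of nhr-19, nhr-46, nhr-34, nhr-3, sea-2, unc-108 (72.03), hlh-30 and mdl-1. Summits outside promoter windows entered no list test.

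In the list of the tagged factor and its network, mdl-1 was the only gene with a thresholded region in its promoter window. The promoter windows of its relatives held relaxed regions that did not pass, or none. The highest was at mxl-3, with a pooled signal of 34.7 (rank 1045), followed by mxl-1, which encodes the MAX-like partner of MDL-1, at 25.15 (rank 6297), and mxl-2 at 19.2. No pooled relaxed region lay in the promoter windows of mml-1, hlh-30 or klu-1, and unc-119 had one with a signal of 18.7. Inside hlh-30, however, 2 thresholded regions lay in an intron, outside the promoter window. One, at 4025911 to 4026250 on chromosome IV, had a signal of 70.6 (rank 117) and a CACGTG, and the other, at 4028175 to 4028514, had 53.98 (rank 216). Their ranks in replicate 1 were 500 and 2776, and in replicate 2 100 and 208.

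The thresholded list held 259 regions in ce11 and 236 in ce10. By rank order, 230 of the first 236 signal values lay on the same chromosome and within 0.1% in both builds, while none matched exactly in signal and width. The usual region width was 340 bp in both builds for the pooled list and replicate 2, and 330 bp in ce11 but 336 bp in ce10 for replicate 1. For replicate 1 only 12 of the first 236 values matched within 0.1%.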

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

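Promoter location kept its direction and side of the threshold in all 11 alternatives (odds ratios 1.54 to 2.81), CACGTG in all 12 (5.95 to 18.2), and agreement of the strongest regions in all 5 (36.5% to 58.9%). Merging summits within 100 bp, counted among the alternatives for promoter location, chromosome X, CACGTG and the gene lists, left all 259 regions. It repeated the main values, so it adds nothing to these counts. The excess at mdl-1 held in all 5. The odds ratio of chromosome X passed in 7 alternatives (1.56 to 1.97). It no longer passed without 50 kb around mdl-1 and ZK337.2, at 1.35, nor there over strata of GC content, an alternative added after seeing the data, at 1.44; the unadjusted 95% interval of the latter, 1.07 to 1.93, excludes 1, and the loss is one of adjustment over 6 chromosomes. The number of gene lists past the threshold, 3, ranged from 1 to 4 with a replicate left out. It was 1 without the top 10% of regions by signal and 1 with windows of 500 bp up and 200 bp down; the ribosomal protein genes passed in all 9 alternatives. The stricter list by signal holds 130 regions by construction. The rank correlation of 0.186 was 0.231 with summit windows of 25 bp and 0.438 at thresholded regions. At klu-1, within 10 kb there were 6 regions, below the random median of 7, and with a replicate left out the mean signal was 11.7 to 13.9, the lower value below its random median of 11.86, both far from the threshold. No exact match between builds became 230 by rank order. Apart from the changes fixed by construction, the cause was not tested. No paired analysis was possible because there is 1 group. Depth is unknown and could change the ranks of weak regions. The number of regions in each relaxed list, 30000, is fixed.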

Other observations

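The tests of the sequence CGTCTC, of small RNA genes and of the mdl-1 neighbourhood in this part, and all odds ratios over GC content, were chosen after the result they follow up was seen. Regions also lay at genes of small nuclear and nucleolar RNAs. Within 200 bp of the 5' end of a small nuclear RNA gene lay 6 of 259 thresholded summits against 22 of the others (Fisher's exact test, odds ratio 32.04, adjusted p = 8.8e-07, over 7 gene classes). These 6 summits lay at 5 places, since 2 were at sls-2.4, the weaker of them ranking 4429 in replicate 2. Another of the 6, at sup-39, was also the region counted for eif-2Bgamma among the translation factors. With summits within 1000 bp merged, 5 of 251 thresholded regions remained against 17 of the others (Fisher's exact test, odds ratio 29.1, adjusted p = 1.7e-05). For small nucleolar RNA genes the counts were 6 and 76 (Fisher's exact test, odds ratio 9.26, adjusted p = 0.000277). The genes included sls-2.4 (signal 75.6), sls-2.1 (67.5) and sls-2.2 (62.6), which encode the spliced leader SL2 RNA, and the small nucleolar RNA gene ZK484.9 (133.3), whose region ranked 23 in replicate 1 and 82 in replicate 2. The region at sls-2.2 ranked 93 in replicate 2 and 4448 in replicate 1. Small RNA genes of the piRNA class were near 1 thresholded summit and 3.46% of the others (Fisher's exact test, odds ratio 0.108, adjusted p = 0.00659). Thresholded windows were richer in GC (mean 49.7% against 36.3%), and the small RNA tests were not made over strata of GC content.

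The E-box enrichment was set against base composition and location. Thresholded summit windows had a mean GC content of 49.7% (SD 6.60), against 36.3% (SD 8.25) for the others. Over strata of GC content the odds ratio of CACGTG was 6.34 (95% interval 4.64 to 8.67), below the 14.3 without strata, and among summits in promoter windows it was 12.99 (95% interval 8.04 to 20.4). Neither GC content nor promoter location therefore accounts for the whole excess, though the odds ratio was lower within strata of GC content. Direct binding of a bHLH factor such as MDL-1 is a candidate explanation of the rest, and no other strain was analysed here to test it.

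The crowding of regions at mdl-1 may reflect extra copies of the locus in the strain, binding there, or both. Of the 22 regions within 20 kb that neither passed the threshold nor held CACGTG, 17 (77.3%, 95% interval 54.6% to 92.2%) had a signal above the median of chromosome X, 20.5. Raised signal away from E-boxes could come from extra copies, but spread from strong sites nearby would give it too. Regions were derived together with a control, and whether the control carried the same copies was not examined. The control library that would part these was not analysed here. CACGTG was at 6 of the 13 thresholded regions near mdl-1 (46.2%) and at 23.98% of the others (Fisher's exact test, odds ratio 2.72, 95% interval 0.721 to 9.81, p = 0.0972), and 13 regions are too few to decide. No crowding was seen at klu-1, the other gene in the labels.

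Of all 2080 sequences of 6 bases, 426 were more frequent and 287 less frequent at thresholded summits after adjustment. CACGTG had the smallest p, followed by GAGAGA (36.3% against 6.34%), its overlapping form AGAGAG, and CGTCTC (25.9% against 3.24%). On the other strand CGTCTC reads GAGACG, which can overlap the end of GAGAGA. AGAGAC, which bridges them, came next (28.2% against 4.06%). Whether GAGAGA and CGTCTC are parts of a longer sequence was not tested. Over strata of GC content the odds ratio of CGTCTC was 3.27 (95% interval 2.42 to 4.41), so GC content does not account for all of it. A hypothesis that CGTCTC marks a class of sites apart from the E-box sites, written before its test, could not be decided. CGTCTC was at 27.7% of thresholded regions with CACGTG and 25.3% of those without (Fisher's exact test, odds ratio 1.13, 95% interval 0.564 to 2.21, p = 0.744). CACGTG alone was found at 47 regions, CGTCTC alone at 49, both at 18 and neither at 145. GAGAGA and the other sequences that overlap CGTCTC were not part of this split, so regions with neither may hold them.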
